A study of Mus musculus with 7 samples.

How the data were processed

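RNA was measured in 7 samples of mouse pancreatic islets, 4 from control littermates and 3 from mice with a beta cell-specific deletion of FoxO1, FoxO3 and FoxO4. Per the labels, the animals were of a mixed genetic background, cohorts were littermates matched for age and sex, total RNA was extracted with Trizol, and biotin-labelled material was prepared by a Nugen protocol. Groups and sample numbers were taken from the sample titles. The numbers are not shared between groups, so no samples were paired, and the labels name no batch. A further mark in the knockout titles is not explained in the sources used here and was not interpreted.

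The authors deposited log2 expression values, 1 per transcript-level probe set and array, made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA is a method that subtracts background, normalizes arrays to each other and summarises the probes of each set. The log2 scale was read from the values, which ran from 2.50 to 14.3, since no header states it. The software version, its settings and the genome build are not given in the sources used here, so no coordinates are printed. RMA gives no detection call, so a dim probe set keeps a value, and a probe set that is near saturation, such as that of an abundant hormone, understates differences. The medians of the arrays lay between 7.11 and 7.29. Their upper quartiles were 8.63 in control 3 and 8.81 in control 4, and between 8.88 and 8.95 in the other samples, so bright probe sets were not fully matched. Correlations across the 14807 named genes described below ran from 0.980 to 0.995 between control samples and from 0.989 to 0.994 between knockout samples. Between groups they ran from 0.967 to 0.995, and no 2 samples were identical. The number of arrays limits the precision.

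Of 23238 probe sets, 14939 had 1 gene symbol in the platform annotation, 989 had several and 7310 had none. Only those with 1 symbol named a gene. Of them 14884 matched the RefSeq annotation of GRCm38.p6 by Entrez ID, which changed 0 symbols, and 55 kept the platform's symbol. A gene with several probe sets, of which there were 131, was represented by the one with the highest mean, giving 14807 genes. Some genes of interest, among them Ins1, Abcc8 and Irs2, were not analysed here.

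Knockout and control samples were compared with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes, two-sided, all 7 samples, no covariates, no filter on dim probe sets), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A standard error is that of the moderated test. Before the data were examined, 28 gene lists were fixed, holding 501 genes of which 402 were measured. The 23 lists with at least 5 measured genes, other than those serving as sample checks, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Camera with a correlation estimated for each list and fry were alternatives. For each list, members past the threshold were counted over all genes and adjusted over the list alone. A correlation estimated from 7 samples takes in any state in which samples of a group differ.

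Named genes followed a rule that was also fixed beforehand. It took the FoxO genes, up to 10 genes in each direction among those past the threshold without overlap, the 4 members of each list with the smallest p, the 3 most abundant members of each cell type list, and a few beta cell, MODY and progenitor genes whatever their test. Since 1 gene was past the threshold, most named genes came from the lists. Alternatives were a filter on genes below the median level, the mean of a gene's probe sets, quantile normalization, centring, a trended and robust prior, array weights, an unmoderated test, all probe sets as separate features, a minimum absolute log2 fold change of 1, and leaving out each sample. A covariate for the immediate early genes and a fit without controls 3 and 4 were added after the data had been seen.

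The scripts were tested on simulated data with the 14807 genes and 7 samples of this comparison, in 10 runs with 200 changed genes. With independent noise 23.4% of genes changed by 0.5 were called, 72.6% of those changed by 1, 91.6% at 1.5 and 95.4% at 2, with 8 unchanged genes called per run. With noise shared along a sample axis the shares were 22.6%, 69.4%, 86.2% and 96.2%, with 1.1 unchanged genes per run. A list shifted by 0.4 was called by camera at the preset correlation in 10 of 10 runs with either noise. With an estimated correlation it was called in 10 runs with independent noise and in 0 with the shared axis. Unshifted lists were called 0.1 and 0.3 times per run at the preset correlation. The simulated noise held at most 1 shared axis, and regroupings of the real samples into 4 and 3, other than by genotype, called up to 10 lists. These rates therefore cannot be taken as the rate of false calls for the real samples. Nor do the shares of changed genes called carry over to them. Those shares hold for 200 changed genes per run, and the adjusted threshold grows stricter when fewer genes change. In the real samples 8 genes had a larger absolute difference than the 1 gene past the threshold. Plots were drawn with matplotlib in Python.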

Results

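Gene expression was measured on Affymetrix arrays in pancreatic islets, the clusters of hormone-secreting cells of the pancreas, from 7 mouse samples. Of these, 4 were islets of control littermates, numbered 1 to 4, and 3 were islets of mice lacking FoxO1, FoxO3 and FoxO4 in the insulin-producing beta cells, numbered 5 to 7. FoxO proteins are transcription factors that insulin signalling keeps out of the nucleus. The single comparison the design implies, knockout against control islets, addresses how loss of these factors alters islet gene expression. The series title places it in the setting of impaired insulin secretion and a diabetes resembling MODY, maturity-onset diabetes of the young, a monogenic form. The labels do not say whether a sample is 1 animal or a pool, so p-values measure only the spread between these samples. Each array gave log2 values for 23238 probe sets, with medians of 7.11 to 7.29, and 14807 named genes were compared. The number of arrays limits the precision, and all differences are knockout minus control on the log2 scale.

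Transcripts of the deleted genes were not past the threshold in knockout islets. Foxo4 was at 6.53 ± 0.32 (SD, n = 3) in knockout and 7.00 ± 0.13 (SD, n = 4) in control islets, a difference of -0.47 (SE 0.16) with no overlap between the groups. Foxo3 differed by -0.16 (SE 0.11), also without overlap, and Foxo1 by -0.26 (SE 0.17) with overlapping values. Foxo6, which was not deleted, differed by 0.07 (SE 0.15). None of the 4 genes passed limma's test over all genes, with adjusted p values of 0.362 for Foxo4, 0.486 for Foxo3, 0.490 for Foxo1 and 0.873 for Foxo6, and none passed when adjusted over the list alone, where Foxo4 had 0.0634. The differences of Foxo1, Foxo3 and Foxo4 were negative under every alternative run for them. After quantile normalization Foxo1 differed by -0.42, Foxo3 by -0.29 and Foxo4 by -0.48, all 3 at an unadjusted p under 0.05 but with adjusted p values of 0.359, 0.362 and 0.359. Without controls 3 and 4 Foxo1 differed by -0.50 (SE 0.15, adjusted p = 0.951). Each gene had 1 transcript-level probe set, the deleted exons are not given in the sources used here, and islets also hold cells that keep the genes, so these values are a weak check of the labels.

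**Figure D1:**
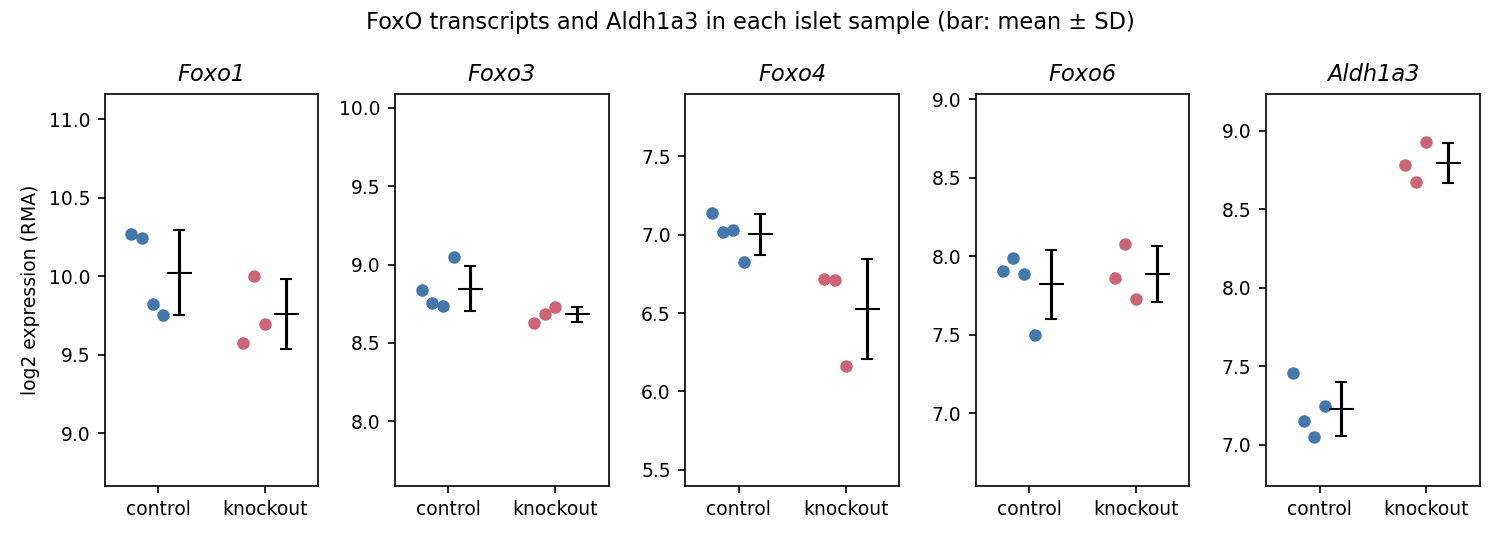
Log2 expression of Foxo1, Foxo3, Foxo4, Foxo6 and Aldh1a3 in 4 control samples (blue) and 3 knockout samples (red), with the mean and SD of each group in black and the same axis span in each panel. Aldh1a3 was at 7.23 ± 0.17 in controls and 8.80 ± 0.13 in knockouts, while Foxo4 was at 7.00 ± 0.13 and 6.53 ± 0.32.

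Aldh1a3, which encodes a retinaldehyde dehydrogenase used as a marker of dedifferentiated beta cells, rose in knockout islets from 7.23 ± 0.17 (SD, n = 4) to 8.80 ± 0.13 (SD, n = 3). The difference was 1.57 (SE 0.12), a fold of 2.96, and all 3 knockout samples lay above all 4 controls. It was the single gene of 14807 past the threshold (limma, adjusted p = 0.0164), and 0 genes were lower. At an unadjusted p under 0.05 there were 2028 genes, against 740.35 that chance gives, of which 1711 were higher and 317 lower in knockout islets. This count was 569 without knockout 5, 852 without knockout 6, 1024 without control 4, 1212 without control 3, 3122 without control 1 and 700 without controls 3 and 4. Of the 121 genes of the naming rule, 61 had a difference over 1.5 times smaller without controls 3 and 4, which lay apart from the other samples, 10 one over 1.5 times larger, 17 one of the other sign and 33 one within 1.5 times, Aldh1a3 among these last. The share that was higher was 84.4% in the values as deposited, 64.3% after quantile normalization and 78.3% with each sample centred on its median. The groups did not overlap for 1618 genes, 10.9% of those tested, where chance gives 5.71%. The difference for Aldh1a3 was 1.49 to 1.64 under every alternative setting, but its call was lost without control 2 (adjusted p = 0.104), control 4 (0.133), knockout 5 (0.228), knockout 6 (0.134) or knockout 7 (0.0993), with an unmoderated test (0.528), without controls 3 and 4 (0.156, an alternative chosen after seeing the data) and when all 23238 probe sets were tested (0.0849), in a range of 0.00445 to 0.528 over the alternatives.

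Genes that mark beta cell identity did not pass as a group. Of 21 measured members, 10 had positive and 11 negative differences, with a median of -0.004 and a mean of 0.03. Ins2, an insulin gene, differed by 0.22 (SE 0.12), Pdx1 by -0.04 (SE 0.19) and Mafa by -0.004 (SE 0.17), the latter pair encoding transcription factors of mature beta cells, and none passed limma's test (adjusted p = 0.423, 0.946 and 0.992). G6pc2, the islet glucose-6-phosphatase, had the smallest p of the list, with a difference of 0.39 (SE 0.17, adjusted p = 0.364). Tested by camera against all other genes, the beta cell list lay lower with an adjusted p of 0.193, or 0.995 with an estimated correlation. With single samples left out its median ran from -0.04 to 0.05. It passed after quantile normalization (median -0.18, adjusted p = 0.0461) and without knockout 7 (median -0.04, adjusted p = 0.0173), in a range of 0.0173 to 0.995 over 18 alternatives.

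Among 10 measured MODY genes, 0 passed the test over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Hnf4a, a nuclear receptor mutated in a form of MODY, differed by 0.27 (SE 0.29, limma, adjusted p = 0.707), a sign that turned in 2 of 16 alternatives. Appl1, an adaptor in insulin signalling, differed by 0.28 (SE 0.14) and Klf11 by -0.18 (SE 0.15). The list's median was 0.07 and its mean 0.08, though the median was -0.03 without control 4 and 0.13 without control 2, while camera placed it below other genes (adjusted p = 0.877, and 0.995 with an estimated correlation). Of 21 genes that mature beta cells normally keep silent, 0 passed either adjustment and 0 had an unadjusted p under 0.05. Their median was 0.04 and mean 0.03, with medians of -0.03 without knockout 5 to 0.10 without knockout 7, against a camera direction below other genes (adjusted p = 0.355, and 0.995 with an estimated correlation). Cd44 differed by 0.31 (SE 0.24) and Igfbp4 by -0.21 (SE 0.11).

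Progenitor and dedifferentiation genes held 1 member that rose over all genes tested, Aldh1a3, and 2 adjusted over the list alone. The other was Serpina7, which encodes thyroxine-binding globulin and was at 9.998 ± 1.16 (SD, n = 3) in knockout and 7.27 ± 1.31 (SD, n = 4) in control islets. Its difference of 2.73 (SE 0.75) had an adjusted p of 0.0393 adjusted over the list alone and 0.362 over all genes in limma. It was at 5.68 in control 3 and 6.72 in control 4, against 8.55 and 8.11 in controls 1 and 2, and without controls 3 and 4 the difference was 1.66 (SE 0.58). Neurog3, the transcription factor of endocrine progenitors, differed by 0.17 (SE 0.13), and Pou5f1, a pluripotency factor, by 0.28 (SE 0.11). Of 12 measured members, 11 had positive differences, with a median of 0.17, which was 0.06 without control 4, 0.07 without knockout 6 and 0.26 without knockout 7. The list as a whole did not pass in camera (adjusted p = 0.193, and 0.995 with an estimated correlation), but passed without control 3 (0.0482) and with an unmoderated test (0.00839), in a range of 0.00839 to 0.995. In fry's test for change in one direction the list, which holds Aldh1a3, had an adjusted p of 0.339, and in that for change in either direction 0.000169, the single list of 23 past the threshold.

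Genes of mitochondrial respiration and fuel oxidation were past the threshold as lists, higher in knockout islets, with camera's preset correlation, although no single member passed. With an estimated correlation each of these lists had an adjusted p of 0.995. The oxidative phosphorylation list, subunits of the respiratory chain and ATP synthase, had positive differences for 27 of 29 measured members and a median of 0.37. Ndufa2 differed by 1.03 (SE 0.30), Ndufs7 by 0.71 (SE 0.22), both subunits of complex I, and Cox7a2 of cytochrome oxidase by 0.67 (SE 0.22), each with an adjusted p of 0.362 in limma. Unadjusted, 12 members were higher and 0 lower. Camera with the preset correlation gave an adjusted p of 6.69e-05 for the list, but an adjusted p of 0.995 with an estimated correlation. Without knockout 5 the median was 0.24, and without controls 3 and 4, which lay apart from the other samples and were left out after seeing the data, it was 0.18, with the call kept in both. Targets of PPAR alpha, a nuclear receptor that drives fatty acid oxidation, and genes of that pathway had positive differences for 23 of 26 members and a median of 0.27 (adjusted p = 0.00594, and 0.995 with an estimated correlation). Among them Fabp3, a fatty acid binding protein, differed by 1.53 (SE 0.41), Acot2, a mitochondrial acyl-CoA thioesterase, by 0.98 (SE 0.32), and Acaa2, which catalyses the last step of mitochondrial beta-oxidation, by 0.75 (SE 0.18). Of this list 9 members were higher and 0 lower at an unadjusted p under 0.05, and 0 passed either adjustment. Its median was 0.17 after quantile normalization and 0.14 without controls 3 and 4, with the call kept in both, and the call was lost when genes below the median level were left out (adjusted p = 0.125, in a range of 0.00246 to 0.995 over 18 alternatives).

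The TCA cycle and antioxidant lists were also past the threshold as higher with the preset correlation. For the TCA cycle, 19 of 21 members had positive differences, with a median of 0.30 (camera, adjusted p = 0.0134, and 0.995 with an estimated correlation). Sdhc and Sdhb, subunits of succinate dehydrogenase, differed by 0.43 (SE 0.15) and 0.40 (SE 0.15), and Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, differed by -0.30 (SE 0.11). The antioxidant list had a median of 0.50 and positive differences for 18 of 21 members (adjusted p = 0.0365, and 0.995 with an estimated correlation). Gpx4, which reduces lipid peroxides, differed by 0.75 (SE 0.25), and catalase, Cat, by 0.53 (SE 0.15). Unadjusted, 4 TCA genes were higher and 1 lower, 5 antioxidant genes were higher and 0 lower, and 0 members of either list passed an adjustment. The TCA call was lost without control 3 (median 0.17, adjusted p = 0.0618), without controls 3 and 4 (0.14, 0.166), with quantile normalization (0.17, 0.316), array weights (0.18, 0.0627) or the filter on genes below the median level (0.30, 0.188), in a range of 0.00607 to 0.995 over 18 alternatives. The antioxidant call was lost without control 2 (adjusted p = 0.0538), control 3 (0.106, median 0.33), knockout 5 (0.0968), knockout 7 (0.0883) or controls 3 and 4 (0.231, median 0.09), and with the filter (0.131), array weights (0.124, median 0.33) or an unmoderated test (0.0936), in a range of 0.00700 to 0.995.

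**Figure D2:**
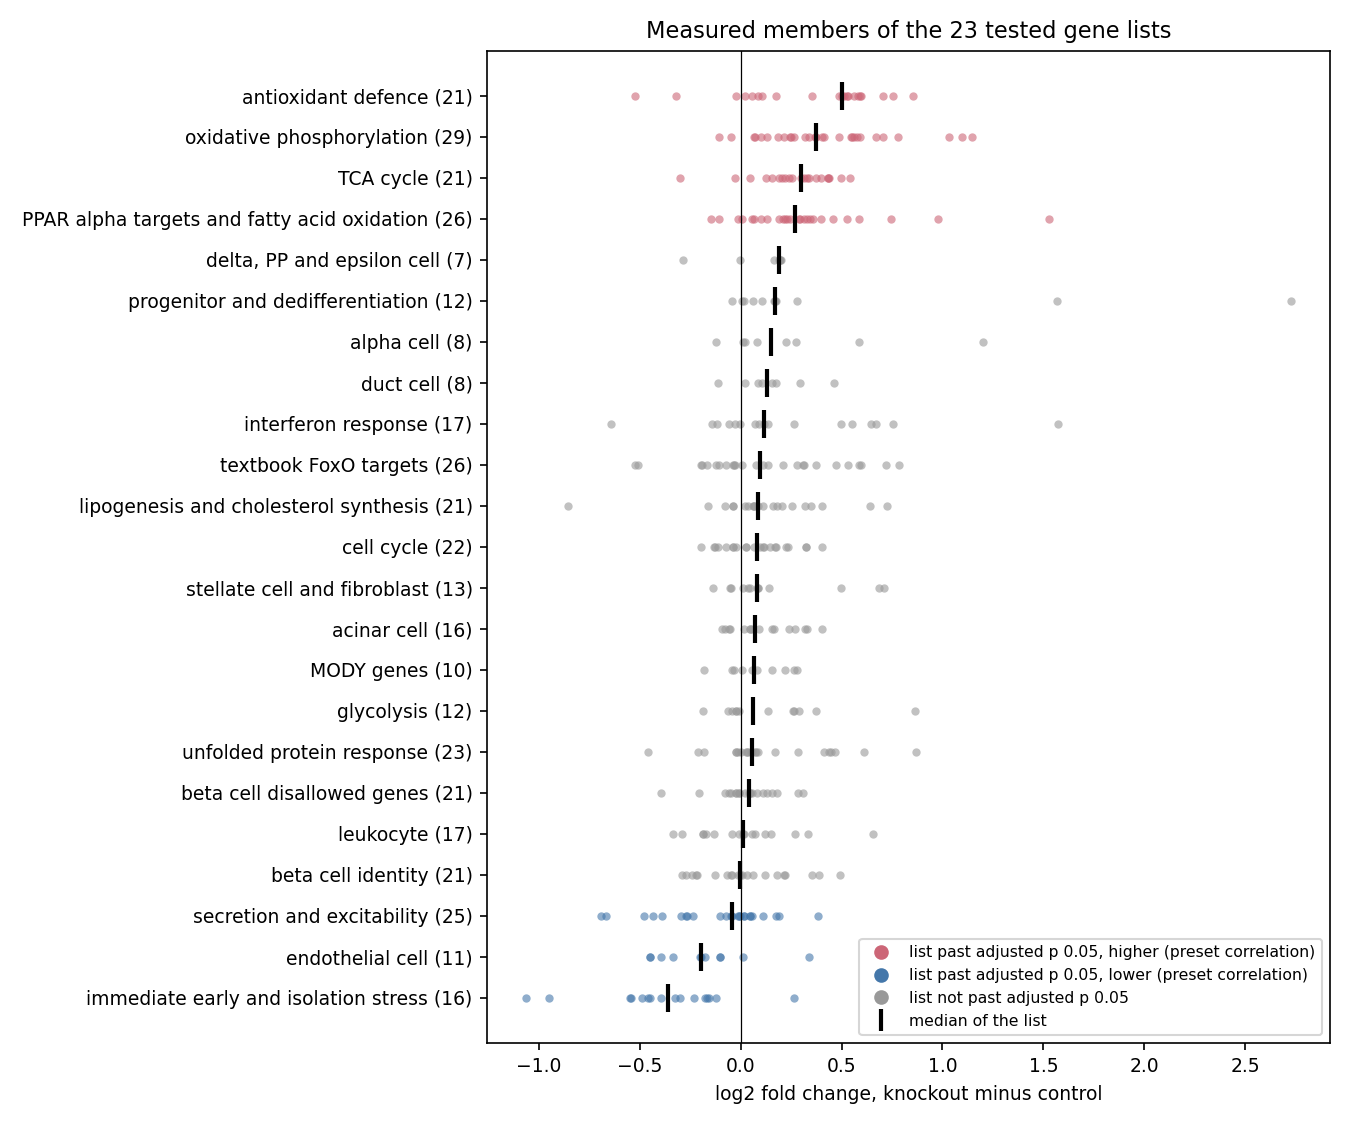
Log2 fold change, knockout minus control, of each measured gene in the 23 tested lists (points, number of genes in brackets), with each list's median as a black bar. Lists past an adjusted p of 0.05 in camera with the preset correlation are red (4 higher) or blue (3 lower). With an estimated correlation 0 lists passed.

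The glycolysis, lipid synthesis, FoxO target and unfolded protein response lists did not pass the test against other genes. Of 12 glycolysis genes 4 were higher at an unadjusted p under 0.05, including Tpi1, triosephosphate isomerase, by 0.87 (SE 0.30), and Aldoa, an aldolase, by 0.38 (SE 0.16), but the list's median was 0.06 (camera, adjusted p = 0.863, and 0.995 with an estimated correlation). Of 21 lipogenesis and cholesterol synthesis genes 1 was lower unadjusted, Mlxipl, which encodes the glucose-responsive factor ChREBP, with a difference of -0.86 (SE 0.28). Scd1, a stearoyl-CoA desaturase, differed by 0.72 (SE 0.35), and the list's median was 0.09 (camera, adjusted p = 0.988, and 0.995 with an estimated correlation). Genes commonly cited as FoxO targets had a median of 0.10 and a mean of 0.14 over 26 members, with a camera direction below other genes (adjusted p = 0.877, and 0.995 with an estimated correlation). Bnip3, a mitophagy receptor, differed by 0.31 (SE 0.12) and Gadd45a, a stress-response gene, by 0.47 (SE 0.20). The unfolded protein response list, 23 genes, had a median of 0.06 and a mean of 0.14, again with a camera direction below other genes (adjusted p = 0.958, and 0.995 with an estimated correlation), and Xbp1, a transcription factor of that response, differed by 0.44 (SE 0.22). In these 4 lists 0 members passed the test over all genes or adjusted over the list alone. Without controls 3 and 4 the differences were 0.15 (SE 0.16) for Scd1, 0.08 (SE 0.12) for Xbp1, -0.42 (SE 0.19) for Mlxipl and 0.48 (SE 0.27) for Tpi1. With single samples left out the medians ran from 0.04 to 0.14 for glycolysis, 0.02 to 0.16 for lipid synthesis, 0.03 to 0.17 for FoxO targets and 0.02 to 0.13 for the unfolded protein response. The glycolysis median was 0.26 when genes below the median level were left out, still short of the threshold (camera, adjusted p = 0.900).

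Genes of insulin secretion and electrical excitability were lower as a list in camera with the preset correlation (adjusted p = 0.000129). The adjusted p was 0.727 with an estimated correlation and 0.535 with fry. Of 25 measured members, 16 had negative differences, with a median of -0.04 and a mean of -0.12, against a median of 0.08 for all genes. Cacna1c, a pore-forming subunit of L-type calcium channels, was at 9.38 ± 0.43 (SD, n = 3) in knockout and 10.05 ± 0.27 (SD, n = 4) in control islets, a difference of -0.67 (SE 0.22). Ptprn, a protein of the insulin granule membrane, differed by -0.39 (SE 0.14), and Stx1a, a syntaxin of the exocytosis machinery, by -0.27 (SE 0.10), whereas its partner Snap25 differed by 0.38 (SE 0.14). At an unadjusted p under 0.05, 7 members were lower and 1 higher, and 0 passed the test over all genes or adjusted over the list alone. The call was kept when single samples were left out, but the median then ran from -0.009 without control 1 to -0.07 without knockout 7, and it was -0.20 after quantile normalization and -0.10 without controls 3 and 4.

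Immediate early genes, which respond within minutes to stimulation or tissue handling, fell as a list, with negative differences for 15 of 16 members and a median of -0.36 (camera, adjusted p = 2.68e-05, and 0.995 with an estimated correlation). Fos was at 10.58 ± 1.00 (SD, n = 3) in knockout and 11.64 ± 0.98 (SD, n = 4) in control islets, and Ier2 at 7.78 ± 0.43 and 8.73 ± 1.18. No member had an unadjusted p under 0.05, so 0 passed either adjustment. The mean over the list was 11.06 in control 3 and 10.999 in control 4, against 10.50 in control 1, 10.04 in control 2, 10.16 in knockout 5, 9.86 in knockout 6 and 10.78 in knockout 7. Controls 3 and 4 also lay apart on the first principal component, at 43.2 and 30.3 where the other 5 samples lay between -29.0 and -3.40, and that component held 64.7% of the variance. In the same samples the mean of the oxidative phosphorylation list was 9.18 in control 3 and 9.30 in control 4, against 9.68 and 9.62 in controls 1 and 2 and 10.02, 9.94 and 9.65 in knockouts 5, 6 and 7. The antioxidant means were 8.61 and 8.84 in controls 3 and 4, against 9.28 and 9.07 in controls 1 and 2 and 9.44, 9.28 and 9.15 in knockouts 5, 6 and 7. The immediate early median was -0.16 without knockout 6, -0.24 without control 3, -0.60 without control 2 and -0.68 without knockout 7, with the call kept in each. Without controls 3 and 4 it was 0.01 and its call was lost (adjusted p = 0.307, in a range of 1.93e-09 to 0.995 over 17 alternatives).

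**Figure D3:**
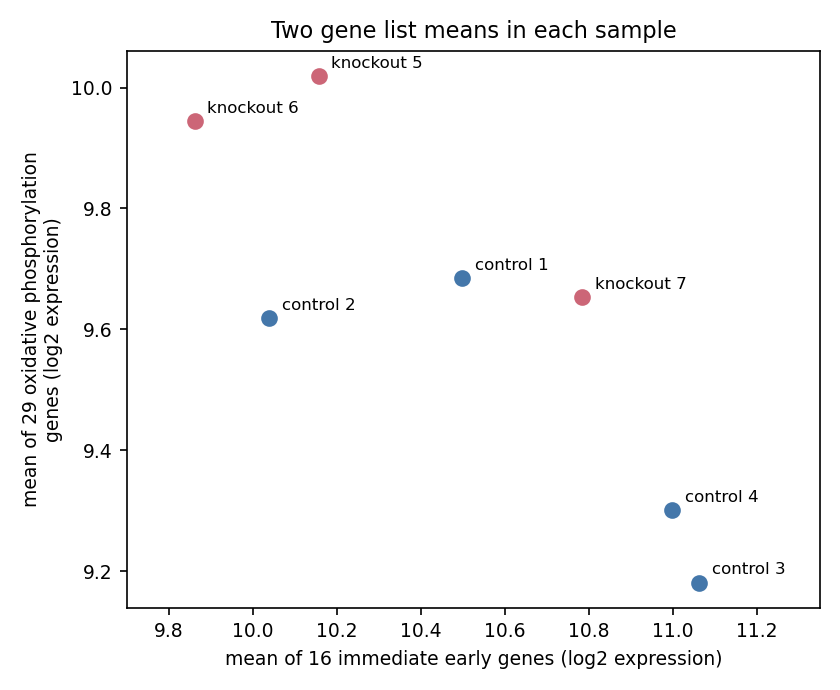
Mean log2 expression of the 29 oxidative phosphorylation genes (vertical axis) against that of the 16 immediate early genes (horizontal axis) in each of 4 control (blue) and 3 knockout (red) samples. Controls 3 and 4 sit at 11.06 and 10.999 on the horizontal axis, with oxidative phosphorylation means of 9.18 and 9.30.

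Interferon response and cell cycle genes did not pass as lists. The 17 interferon genes had a median of 0.12 and a mean of 0.26, the median running from -0.10 without control 3 to 0.41 without control 2, with a camera direction below other genes (adjusted p = 0.771, and 0.995 with an estimated correlation). Ifit1, an antiviral gene induced by interferon, was at 11.10 ± 0.92 (SD, n = 3) in knockout and 9.53 ± 1.79 (SD, n = 4) in control islets, a difference of 1.57 (SE 0.90, limma, adjusted p = 0.435) that was 0.11 (SE 0.52) without controls 3 and 4. Stat2, a transcription factor of the interferon pathway, differed by -0.64 (SE 0.26). The 22 cell cycle genes had a median of 0.08, which ran from -0.02 without control 4 to 0.23 without control 1, with a camera direction below other genes (adjusted p = 0.652, and 0.995 with an estimated correlation), and Tyms, thymidylate synthase, differed by 0.32 (SE 0.12). In both lists 0 members passed the test over all genes or adjusted over the list alone. Without controls 3 and 4 the interferon list (median -0.29) and the cell cycle list (median -0.13) were past the threshold as lower, each with an adjusted p of 6.29e-05, the lowest of a range reaching 0.995, and both passed with the immediate early mean as a covariate, at 0.000182 and 0.0290.

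Endothelial markers fell as a list among the markers of other islet cell types. Differences were negative for 9 of 11 members, with a median of -0.20 (camera, adjusted p = 6.69e-05, and an adjusted p of 0.727 with an estimated correlation). The vascular growth factor receptors Flt1 and Kdr each differed by -0.45 (SE 0.14 and 0.17), and Egfl7, an endothelial secreted protein, by -0.39 (SE 0.15), while Emcn, endomucin, differed by 0.34 (SE 0.22). Unadjusted, 3 members were lower and 0 higher, and 0 passed either adjustment. Without controls 3 and 4 the median was -0.30, with the call kept.

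Markers of the remaining cell types had 0 members past the test over all genes or adjusted over the list alone. The alpha cell list had a median of 0.15 over 8 genes (camera, adjusted p = 0.744), which was 0.02 without control 4, 0.27 without knockout 7 and -0.01 without controls 3 and 4. Its members included Gcg, the glucagon gene, at 0.02 (SE 0.08), and Pou3f4, a transcription factor of alpha cells, at 1.20 (SE 0.39), the latter with an adjusted p of 0.362 in limma. Delta, PP and epsilon cell genes had a median of 0.19 and a camera direction below other genes (adjusted p = 0.988), with Sst, somatostatin, at -0.005 (SE 0.09) and Ppy, pancreatic polypeptide, at 0.16 (SE 0.11). Acinar genes, which encode digestive enzymes, had a median of 0.07 and a camera direction below other genes (adjusted p = 0.863), with Prss2, a trypsinogen, at 0.32 (SE 0.37) and Cpa1, carboxypeptidase A1, at -0.05 (SE 0.35). Without control 4, whose acinar mean was 7.82 where the other controls lay between 8.53 and 8.92, the acinar list was lower (median -0.14, adjusted p = 0.00527, the lowest of a range reaching 0.995). Duct genes had a median of 0.13 (adjusted p = 0.877), with Krt19, a keratin, at 0.29 (SE 0.16), and stellate and fibroblast genes one of 0.08 (adjusted p = 0.988), with Rgs5, a pericyte marker, at 0.71 (SE 0.22). Leukocyte genes had a median of 0.01 and a camera direction below other genes (adjusted p = 0.238), with Fcer1g, an Fc receptor chain, at 0.66 (SE 0.26) and Cd68, a macrophage marker, at -0.19 (SE 0.11), and passed as lower without control 3 (median -0.11, adjusted p = 0.00826), without controls 3 and 4 (-0.21, 0.000249), with array weights (-0.16, 0.00284) and with the immediate early covariate (-0.07, 0.0290), in a range reaching 0.995. Leaving out single samples moved the medians of the delta, PP and epsilon cell list between 0.09 and 0.23, of the acinar list between -0.14 and 0.24, of the duct list between 0.03 and 0.22, of the stellate list between 0.005 and 0.17 and of the leukocyte list between -0.11 and 0.06. With an estimated correlation each of these 6 lists had an adjusted p of 0.995.

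Lists with fewer than 5 measured genes were read as values. The 4 Schwann cell genes differed by 0.07 to 0.15 and the red blood cell genes Alas2 and Slc4a1 by 0.22 (SE 0.29) and 0.11 (SE 0.17). The Y-linked genes Kdm5d and Eif2s3y were at 8.20 ± 0.14 (SD, n = 4) and 10.003 ± 0.11 (SD, n = 4) in control and 8.39 ± 0.07 (SD, n = 3) and 10.18 ± 0.19 (SD, n = 3) in knockout islets. The strain-variable genes Nnt, a mitochondrial transhydrogenase, and H2-Ea differed by 0.22 (SE 0.13) and 0.06 (SE 0.14). None of these 10 genes passed limma's test, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05.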

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

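The comparison of other cell types' markers with Aldh1a3, the choice of the 4 lists weighed together, the splits for the unadjusted count and the fit without controls 3 and 4 were settled only after the results had been seen. The remaining tests here were set down before they were run, though after the genes' and lists' values were known.

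Within the 4 controls, 3 of 150 values tested had 1 sample far from the others, fewer than the 1 in 20 that chance gives. The test looks for 1 sample apart from the rest, so it cannot see 2 samples that move together. Controls 3 and 4 did so on the first principal component, at 43.2 and 30.3 against -8.37 and -7.01 in controls 1 and 2. The low count is thus no sign that the controls were alike. Pfkm, a muscle-type phosphofructokinase, was at 9.12 in control 1 and between 8.74 and 8.79 in the other controls. Sdhb was at 9.21 in control 3 and between 9.49 and 9.55 in the others. The mean of the beta cell identity list was 11.15 in control 1 and between 10.97 and 10.99 in the others.

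For the 2028 genes at an unadjusted p under 0.05, 6 of 35 splits of the samples gave at least as many, the real one included, and the highest other gave 3891, so chance is not excluded for that count.

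Aldh1a3 was higher in all 3 knockout samples than in any control, by 1.57. A sample state tracked by the immediate early genes is argued against, since with their mean as a covariate the difference was 1.59 (95% interval 1.27 to 1.90). More acinar, duct, endothelial, stellate or leukocyte cells are argued against too, for each list as a whole. The highest upper quartile of log2 differences among their marker lists was 0.25, where 0.78 was the bound set from the difference of Aldh1a3. Abundant acinar genes such as Prss2 (0.32) and Cpa1 (-0.05) stayed far below. Single members came nearer, Rgs5 at 0.71 and Dcn at 0.69 (stellate) and Fcer1g at 0.66 (leukocyte), so a rise of a subtype within a list is not excluded. Of the 65 genes in those 5 lists, 3 are in another list and 40 lie above the median gene of these islets. Alpha cells were not part of this comparison. Their list had an upper quartile of 0.35, with Pou3f4 at 1.20 and Gcg at 0.02. Chance is not excluded for the number of genes called, because 2 of 35 splits of the samples into 4 and 3 gave at least the real count of 1, and the split that set controls 3 and 4 with knockout 7 gave 5, none of them Aldh1a3, which points to a structure of the samples behind that count. For Aldh1a3 itself the difference was 1.49 without controls 3 and 4, where its call was lost (adjusted p = 0.156), and an effect of the FoxO deletion on it may be put forward as a hypothesis, found and tested on the same data.

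The respiration, fatty acid oxidation, TCA cycle and antioxidant lists were higher in knockout islets, with a median difference of 0.33 over their 97 genes, but each call was lost with an estimated correlation (adjusted p = 0.995) and with fry (0.339 to 0.415). A linear trend with gene length, taken as the genomic span of the gene, is argued against. Its slope was -0.005 per log10 of length (Pearson r -0.012 and Spearman rho -0.019 across 14780 genes, which are not independent). Without that trend 100.3% of the median relative to all genes was left. The length of the transcript was not tested, so a trend with it is not excluded. A state tracked by immediate early genes cannot be told apart from the genotype: with the covariate 61.1% of the median was left (0.33 to 0.20), but 34.2% to 79.1% with single samples left out. Chance is not excluded, because 18 of 35 splits called at least the real 7 lists and the highest other called 10. A change of fuel oxidation through the FoxO deletion remains open and may be one source of these shifts. The handling or state of controls 3 and 4 may be another, as may the incomplete matching of bright probe sets, which was not tested as a cause. Quantile normalization lowered the medians from 0.37 to 0.25 for respiration and from 0.27 to 0.17 for fatty acid oxidation. It lowered them from 0.30 to 0.17 for the TCA cycle and from 0.50 to 0.36 for the antioxidant list. Among genes above the median level only the respiration call was kept.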

How the results depend on the processing

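The immediate early covariate and the fit without controls 3 and 4 were chosen after the data had been seen; the other alternatives were planned.

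The count of genes past the threshold, 1 as reported, stayed at 1 with the filter, the mean of probe sets, quantile normalization, centring, the trended prior, the fold minimum and the covariate. It was 2 with array weights (Aldh1a3 and 6330403K07Rik), 0 with the unmoderated test, 0 with all probe sets and 0 without controls 3 and 4, with 2573, 1104, 2512 and 700 at an unadjusted p under 0.05. Leaving out single samples gave 0 to 1, with Aldh1a3 called without controls 1 or 3 and lost without controls 2 or 4 or any knockout. Fits without a sample hold fewer samples; the cause was not tested further. No FoxO transcript tested was past the threshold under 16 alternatives, of which the filter left out Foxo4. The 7 lists past the threshold became 4 with the filter, 0 with an estimated correlation and 0 with fry, and 6 to 9 elsewhere; the cause was not tested. The oxidative phosphorylation, endothelial and secretion calls were kept in 16 of 18 alternatives, all but the estimated correlation and fry, and the PPAR alpha call in 15, the immediate early call in 14 of 17, the TCA call in 11 and the antioxidant call in 8.

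Over 140 named genes, 2204 values under alternatives held 2196 on the same side of the threshold, 7 weaker, 1 stronger and 0 reversed. Only Aldh1a3 was past the threshold as reported, so the other genes had no call to lose and the high agreement says little. Aldh1a3 kept its call in 9 of 16 alternatives. Over 23 lists, 412 values held 370 on the same side, 29 weaker, 13 stronger and 0 reversed in camera's direction. Values that were never past the threshold and turned sign, 65 in 26 genes and 50 in 15 lists, are counted as on the same side. Ctrb1, Clps, Krt18 and Eif2s3y turned sign with quantile normalization. Scaling moved the median difference of all genes from 0.08 to 0.04 at most. Signal over background could not be judged, since RMA values carry no detection call.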

Other observations

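The 6 genes picked by p, and the random windows, splits and directions used for the neighbours of the FoxO genes were chosen only after the results had been seen.

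A further 6 genes were picked from the 20 with the smallest p, not in rank order, each short of the threshold and without overlap between groups. Penk, which encodes the precursor of the enkephalin opioid peptides, was at 7.53 ± 0.31 (SD, n = 3) in knockout and 6.49 ± 0.30 (SD, n = 4) in control islets, a difference of 1.04 (SE 0.20). Dcx, doublecortin, a microtubule-binding protein of migrating neurons, differed by 0.63 (SE 0.12), and Scd3, a stearoyl-CoA desaturase, by 1.06 (SE 0.22). S100a4, a calcium-binding protein, differed by 0.76 (SE 0.15) and Sult1c2, a sulfotransferase, by 0.98 (SE 0.13). 6330403K07Rik had the smallest p among lower genes, with a difference of -1.34 (SE 0.16) and an adjusted p of 0.228 in limma, where the other 5 had 0.306 to 0.362. These signs held under every alternative run, but without overlap between groups they could not turn when samples were left out or reweighted. The gene 6330403K07Rik passed in limma with array weights (adjusted p = 0.0235, in a range of 0.0235 to 0.769).

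Interferon-induced genes spanned more among the controls than the group means differed, as did every other tested list but the progenitor and secretion lists. A range over 4 single samples is wide by nature beside a difference of group means, so this comparison does not test the differences. The oxidative phosphorylation means spanned 0.50 among controls against a difference of 0.43, and the antioxidant means 0.67 against 0.34. For the progenitor list the values were 0.42 and 0.45, and for the secretion list 0.09 and -0.12. The mean of the 17 interferon genes was 8.001, 8.78, 7.06 and 7.47 in controls 1 to 4 and 7.997, 8.44 and 7.83 in knockouts 5 to 7, a span of 1.72 among controls against a difference of 0.26 between groups. Among controls Gbp2, a guanylate-binding protein, spanned 2.88, the chemokine Cxcl10 2.75 and Rtp4 2.68.

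Of 8299 probe sets that name no single gene, 0 passed limma's adjusted threshold and 909 had an unadjusted p under 0.05.

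Genes lying beside the deleted FoxO genes were tested as candidate passengers, stretches of the targeted chromosomes that differ between knockout and control animals through breeding. Of the 600 measured genes nearest to Foxo1, Foxo3 and Foxo4, 100 on each side, 116 (19.3%) had an unadjusted p under 0.05, against 1909 of 14177 others (13.5%), an odds ratio of 1.54 (95% interval 1.24 to 1.90, Fisher's exact test, two-sided, p = 9.84e-05). This met the criterion set beforehand, that the share be above that of other genes, and its upper bound also lay under the 2 that had been named for no effect, so the criteria did not separate the outcomes. Sets of random windows of neighbouring genes gave as many in 10000 draws with a one-sided p of 0.0025 (median 79). But 2 of 35 splits of the samples gave as large a difference in share, 5.87 percentage points for the real one and 6.16 for the highest other. That other split set controls 1, 3 and 4 against control 2 and the knockouts. It differs from the genotype split only in the place of control 2, so it is not independent of genotype. Of the 116 neighbours 112 were higher and 4 lower in knockout islets. All genes at that p also leaned higher, 1711 against 317, so this direction does not by itself favour passengers. Passenger genes may contribute but cannot be told apart from a shared state of neighbouring genes.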
